A study of Homo sapiens and Mus musculus with 18 samples.

How the data were processed

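Guide RNA reads were analysed in 18 libraries from a study that joined a pooled CRISPR knockout screen to chromatin immunoprecipitation (ChIP). Per the labels' protocols, Cas9-expressing K562 and MLL-AF9 cells were infected with a pooled lentiviral guide library against chromatin regulators at low multiplicity and selected with puromycin. Cells were then fixed and sonicated, ChIP was done, and guide cassettes were amplified by PCR. The deposited values are raw counts of reads per guide, 1 table per library, and no normalization by the authors is recorded. The submitters' processing notes name bcl2fastq, cutadapt and Bowtie2; versions and settings are not given in the sources used here. Gene names and Ensembl identifiers came from the guide names in the files. Of 1143 human symbols, 1054 matched a current symbol and 71 an older symbol of a single gene in an NCBI RefSeq gene table of assembly GRCh38.p14. That table was used only for names, since no genome build is named in the files, and no coordinates are given. In the mouse library, 4 symbols (Atf7ip, Cdc73, Supt20 and Taf9) occur under 2 identifiers each, and each identifier was treated as a gene. Fam208a and D14Abb1e carry the same identifier and were kept apart as named.

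Guide reads per library ranged from 2843481 to 10788702. Between 3.87% and 7.32% of the reads of a library stood on the line for no guide and were left out. A guide absent from a table was taken to have 0 reads. The PCR reads carry no molecular identifiers and are not independent molecules, so the intervals on shares of reads cover counting error only.

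For each ChIP, the log2 ratio of ChIP over control reads was computed per guide after adding 1 read to each count, and the median guide was set to 0. Guides needed 30 reads in the control library and genes needed 3 such guides. The value of a gene was the mean over its guides, with the SD over guides; n below counts guides. A two-sided permutation test set each gene mean against 100000 draws of as many guides from all guides tested, with Benjamini-Hochberg adjustment over genes at 0.05. The smallest p this test can give is 2e-05. With 1 library per group, count models of a ChIP against its control have no residual degrees of freedom between libraries and were not used. A model across the mixtures with time as a covariate was not fitted. The permutation test compares libraries through separate guides within a culture; it compares those libraries and not conditions, and guides are not biological replicates. Which K562 control belongs to the H3K4me3 ChIP is not stated in the labels: the control labelled for Pol II was paired with the Pol II ChIP and the remaining K562 control with the H3K4me3 ChIP. The difference between the H3K4me3 and Pol II ratios was tested per guide in the same way, and 1 control was set against the other as background.

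In the mixed K562 libraries, guides were assigned to the human or mouse library by their names. Human over mouse reads in the ChIP were divided by the same ratio in the input of that time and expressed relative to DMSO. Intervals of 95% came from 10000 bootstrap draws of guides and cover the spread between guides and counting only.

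Before the data were examined, 19 gene lists were fixed: COMPASS H3K4 methyltransferase subunits, H3K4 demethylases, the DOT1L complex, H2B ubiquitination with the PAF1 complex, H2B deubiquitination with SAGA, the super elongation complex with P-TEFb, transcriptional kinases with Mediator, RNA polymerase II with elongation factors, BET proteins, acetyltransferases of the p300/CBP and MYST families, HUSH with SETDB1 and KAP1, DNA methylation, HDAC corepressors, PRC2, PRC1, SWI/SNF, histone chaperones with H2A.Z exchange, H3K36 methyltransferases and readers, and arginine methyltransferases. The list of HUSH with SETDB1 and KAP1 also held CBX1, CBX3, CBX5, SUV39H1, SUV39H2, EHMT1, EHMT2 and WIZ. Mouse genes were matched by the same symbol regardless of case. The median of a list was placed among 10000 random lists of the same size matched on control reads, as a description of these libraries. A further 7 lists (splicing factors, Integrator, Mediator, TFIID, Pol II subunits, INO80 complex and PRMT5 complex) were chosen after the values had been seen. Genes were named by a rule fixed in advance: up to 10 genes per direction past the threshold, up to 4 members of each list with the largest absolute mean, and 10 regulators of H3K4 and H3K79 methylation in every comparison. A gene named outside it is said to be so.

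The test was checked on simulated counts with 200 of the genes changed. Guide noise in every simulated screen, H3K79me2 included, was drawn from the ratios between the K562 controls at like control reads. The SD over guides was 0.54 between those controls, against 0.61 in H3K4me3, 0.57 in Pol II and 0.70 in H3K79me2. The shares below hold for that narrower noise and do not measure recovery or false calls in the real screens. At a put-in log2 change of -1, 50.0% of 34 changed genes were recovered for H3K4me3, 17.6% of 34 for Pol II and 8.82% of 34 for H3K79me2. At a change of 1, they were 60.6% of 33, 63.6% of 33 and 42.4% of 33. At a change of -2, the shares were 100% of 34, 100% of 34 and 58.8% of 34. Of the genes called in these simulations, 0 of 105 for H3K4me3, 1 of 94 for Pol II and 7 of 75 for H3K79me2 had not been changed. With no gene changed, 0 genes were called for H3K4me3, 0 for Pol II and 1 for H3K79me2. Alternatives covered the control-read minimum (none, 100 reads, or 30 on the mean of ChIP and control), scaling by total reads or by non-targeting guides, 5 added reads, the median over guides, leaving out the guide farthest from the median of its gene, a null drawn from non-targeting guides, and the other or the summed K562 controls. Scaling by total reads or by non-targeting guides shifts all guides of a screen and of its null alike. Neither scaling can therefore change a p-value or whether a gene passes. Guide ranks, and guides centred and scaled on others with like control reads in 20 bins, were added after the data had been seen. So was centring in those bins without scaling for H3K79me2. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.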

Results

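CRISPR-ChIP reads the chromatin state of an integrated guide cassette in cells in which the gene named by the guide has been targeted. A guide that is depleted from a ChIP relative to its control marks a gene whose targeting goes with less of the immunoprecipitated mark at the cassette. In K562, a human chronic myeloid leukaemia line, H3K4me3 and RNA polymerase II (Pol II) ChIPs and a control for each were taken on day 6. In mouse MLL-AF9 cells, an acute myeloid leukaemia model carrying a fusion of the H3K4 methyltransferase gene KMT2A (MLL), an H3K79me2 ChIP and its control were taken on day 9. A further 12 libraries came from K562 cells carrying human or mouse guides. These were the 2 unmixed populations, and 5 inputs and 5 H3K79me2 ChIPs of mixtures in which the human-guide cells had received the DOT1L inhibitor SGC0946 or DMSO. Each group was a single library, so no difference below has a replicate check. Guide reads numbered 2843481 in the H3K4me3 ChIP, 7454663 in the Pol II ChIP, 5421236 and 7841744 in their controls, and 9669026 and 10788702 in the H3K79me2 ChIP and its control. The mixed and unmixed libraries held between 5122750 and 8440040.

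The H3K4me3 ChIP asked which regulators, when targeted, alter H3K4 trimethylation at the cassette. Subunits of COMPASS, the family of complexes that methylates H3K4, lay low as a group. Of 17 measured members 13 lay below 0, the median was -0.23 on the log2 scale, and 0.05% of random matched lists had a lower one. The lowest were RBBP5 (ENSG00000117222), a subunit of the shared catalytic core, at -1.03 ± 0.89 (SD, n = 6 guides, 5 below 0), WDR82, which belongs to the SETD1 complexes, at -0.73 ± 0.80, and the core subunits ASH2L at -0.72 ± 0.94 and WDR5 at -0.68 ± 0.69. No member passed the threshold over all genes tested, and 0 passed when adjusted over the list alone, where the lowest adjusted permutation p was 0.0663. With the median over guides in place of the mean, RBBP5 passed over all genes. DPY30 lay at -0.31 ± 0.35, MEN1 at -0.23 ± 0.38, CXXC1 at -0.16 ± 0.94, KMT2A at -0.13 ± 0.45 and SETD1B at 0.19 ± 0.67 (-0.014 without its farthest guide). Scaling on non-targeting guides, a constant shift within each screen, moved the median of all genes to -0.20 in H3K4me3, -0.14 in Pol II and 0.17 in H3K79me2, and the COMPASS median with it, to -0.42. The same list lay at 0.11 when the Pol II control was set against the other control, where 97.0% of random lists were lower.

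Members of the H2B ubiquitination and PAF1 list all lay below 0 in H3K4me3 (10 of 10), with a median of -0.20 and 1.93% of random lists lower, and PAF1 was lowest at -0.41 ± 0.80. PAF1 lay at 0.11 over the other K562 control, and at -0.51 ± 0.83 in control against control. Targeting of POLR2A (ENSG00000181222), the largest Pol II subunit, gave -1.30 ± 1.15 with 6 of 6 guides below 0, and -0.84 over the other K562 control. Its adjusted permutation p was 0.251 over all genes and 0.0160 adjusted over the list of Pol II and elongation factors alone. With 5 reads added POLR2A passed over all genes (adjusted permutation p = 0.0456). The histone chaperone FACT subunits SUPT16H and SSRP1 from that list of Pol II and elongation factors lay at -0.56 ± 0.85 and -0.55 ± 0.68. The whole list had a median of -0.18 with 0.29% of random lists lower, but it also lay at -0.14, with 0.93% lower, in control against control. SMARCA4, the ATPase of SWI/SNF, lay at -1.22 ± 2.47 and was the single call of its list adjusted over the list alone (permutation p = 0.033 after adjustment); without its farthest guide it lay at -0.22. On the other side, H3K4 demethylases had a median of 0.21, above 99.3% of random lists, with KDM5C at 0.41 ± 0.23, RCOR1 at 0.41 ± 0.82, KDM5B at 0.35 ± 0.39 and KDM1A at -0.29 ± 0.38. RCOR1 lay at 0.12 without its farthest guide, and KDM1A at 0.014 over the other K562 control. The DOT1L complex had a median of 0.26, above 99.0% of random lists, with MLLT10 at 0.35 ± 0.42 and DOT1L itself at -0.19 ± 0.65 (0.047 without its farthest guide). Both lists also lay high in control against control, at 0.12 and 0.15. With scaling on non-targeting guides their medians were 0.025, with 4 of 8 members above 0, and 0.073, with 3 of 5 above 0, and neither had a call over all genes or adjusted over the list alone. HDAC corepressors had a median of 0.12, above 97.4% of random lists, which turned to -0.07 with scaling on non-targeting guides. The other 13 lists lay between percentiles 17.3 and 87.7 of random lists, and each of their medians was below 0 with scaling on non-targeting guides. Their medians were -0.09 for PRC2, -0.08 for H3K36 methyltransferases and readers, -0.07 for PRC1, -0.03 for SWI/SNF, -0.02 for kinases with Mediator, -0.014 for HUSH, -0.0071 for histone chaperones and -0.0066 for DNA methylation. Above 0 lay the super elongation complex at 0.0045, p300/CBP and MYST acetyltransferases at 0.013, SAGA genes at 0.07, BET proteins at 0.08 and arginine methyltransferases at 0.11.

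Over all 1140 genes tested in H3K4me3, 2 rose and 0 fell. MGEA5 (ENSG00000198408), which encodes the enzyme that removes O-linked N-acetylglucosamine, rose to 0.92 ± 0.40 with 6 of 6 guides above 0, and DHX8 (ENSG00000067596), a splicing helicase, rose to 0.96 ± 1.01 with 4 of 6 above 0 (adjusted permutation p = 0.0456 for each). Both calls ended when the other K562 control was used, where MGEA5 lay at 0.32 and DHX8 at 0.69. They were kept in 8 and 6 of 13 alternatives. Those that kept them include both scalings, which cannot change a call, and the null from non-targeting guides, with which 108 genes passed. MGEA5 lay at 0.60 ± 0.52 in control against control. Both calls ended with guides centred and scaled on others with like control reads (adjusted permutation p = 0.354 for MGEA5 and 0.690 for DHX8). The DHX8 guides above 0 had between 94 and 290 control reads, and those below 0 had 631 and 718. In H3K4me3 the tenth of guides with the fewest control reads had a median of 0.38 and an SD of 1.00. Its median was 0.41 in control against control. At an unadjusted p under 0.05 there were 96 genes, 56 lower and 40 higher, against 79 in control against control (48 lower and 31 higher), where 0 genes passed the adjusted threshold.

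The Pol II ChIP asked the same of polymerase occupancy. Genes encoding the polymerase itself lay among the lowest. POLR2A lay at -1.46 ± 0.64 with 6 of 6 guides below 0, POLR2G at -1.21 ± 0.71, POLR2C at -1.11 ± 0.96 and POLR2E at -0.98 ± 0.49. The fixed list of Pol II and elongation factors had 14 of 20 members below 0 and a median of -0.13, with 2.95% of random lists lower. It had 0 calls over all genes and 1 adjusted over the list alone (POLR2A, adjusted permutation p = 0.0496). The 11 measured Pol II subunits were also taken alone, a list chosen after the values had been seen. Of these 11 of 11 lay below 0, the median was -0.98 and 0% of 10000 random lists were lower. In control against control the median was -0.31, but there the Pol II control, over which the Pol II ratio is taken, is the numerator. A low value there raises the Pol II ratio and does not lower it. Of the subunits, 8 fell in the Pol II ChIP when adjusted over the list alone, which is not independent evidence. Among them were 2 genes named after their values were seen, POLR2L at -1.59 ± 0.87 and POLR2K at -2.21 ± 4.19, which rests on 1 of its 4 guides.

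PAF1, which travels with elongating polymerase, rose to 0.64 ± 0.52 in the Pol II ChIP when adjusted over the list alone (permutation p = 0.0222 after adjustment), although its list had a median of -0.01, and lay at 0.11 over the other K562 control. JADE3, a partner of the acetyltransferase KAT7, did so at 0.74 ± 1.11 with 6 of 6 guides above 0 (adjusted permutation p = 0.0125 over its list alone) and lay at 0.22 over the other control and 0.30 without its farthest guide, which had 32 control reads. Neither passed over all genes. SAGA and H2B deubiquitination genes had a median of 0.13 with 11 of 16 above 0, above 99.2% of random lists, and 0 calls by either adjustment; scaling on non-targeting guides brought it to 0.01. The list lay at -0.10, with 11 of 16 below 0 and 5.30% of random lists lower, when the Pol II control, over which the Pol II ratio is taken, was set against the other control. Transcriptional kinases with Mediator had a median of -0.14, with 4.26% of random lists lower. Among single genes, RUVBL1 lay at -1.15 ± 0.59, INO80 at 0.58 ± 0.31 (0.03 over the other control), KDM2A at 0.56 ± 0.32 and WDR61 at 0.42 ± 0.42. MBD2 lay at -1.34 ± 2.98 and TRIM28 at -0.88 ± 2.16, each with 3 of 6 guides below 0 and 1 guide with 0 ChIP reads; without the farthest guide they lay at -0.14 and -0.024. COMPASS subunits had a median of -0.03, higher than 45.9% of random lists, with RBBP5 at 0.17 ± 0.38, WDR5 at 0.16 ± 0.36 and ASH2L at 0.10 ± 0.66 (-0.14 without its farthest guide). The other 16 lists, COMPASS included, lay between percentiles 20.8 and 81.5.

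Over all 1140 genes, 0 passed the adjusted threshold of the permutation test on guide means in the Pol II ChIP, where the lowest adjusted p was 0.148 and 77 genes had an unadjusted p under 0.05. With the median over guides in place of the mean, 9 genes fell: the 6 Pol II subunit genes POLR2A, POLR2C, POLR2E, POLR2G, POLR2H and POLR2L, the helicase gene RUVBL1, and EIF4A3 and PCNA. With guide ranks 7 fell and 2 rose, with a null from non-targeting guides 28 fell and 2 rose, over the other control 2 fell and over the summed controls 1 fell.

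Subtracting the Pol II ratio from the H3K4me3 ratio guide by guide tested whether the marks differed. COMPASS subunits had a median difference of -0.21 with 13 of 17 below 0 and 0.56% of random lists lower. Of these, 0 passed over all genes and 4 were lower when adjusted over the list alone: WDR82, RBBP5 at -1.21 ± 0.77, WDR5 at -0.85 ± 1.03 and ASH2L at -0.83 ± 1.42, each with 5 of 6 guides below 0 and adjusted permutation p between 0.0201 and 0.048. PAF1 lay at -1.06 ± 0.84 and passed over its list alone (adjusted permutation p = 0.0338), whose median was -0.18; with H3K4me3 reads divided by Pol II reads and no control it lay at -0.54, and in control against control at -0.51. MBD2 did so at 1.45 ± 3.25, through 1 guide (0.16 without it). JADE3, which did not pass, lay at -1.09 ± 1.36. Over all genes 1 passed, DHX8, at 2.74 ± 3.43 (adjusted permutation p = 0.0228), with H3K4me3 at 0.96 and Pol II at -1.80 ± 2.98 (-0.59 without its farthest guide, which had 0 ChIP reads). That call ended at 1.41 without the farthest guide, at 1.15 with 100 control reads and at 0.54 with no control. With no control the read minimum fell on the Pol II ChIP and left out the DHX8 guides with 27 and 0 reads there. The value of 0.54 is thus not an effect of leaving out the control alone. Pol II subunits, the list chosen afterwards, had a median difference of 0.54 with 11 of 11 above 0. The other 17 fixed lists lay between percentiles 6.29 and 96.2.

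**Figure D1:**
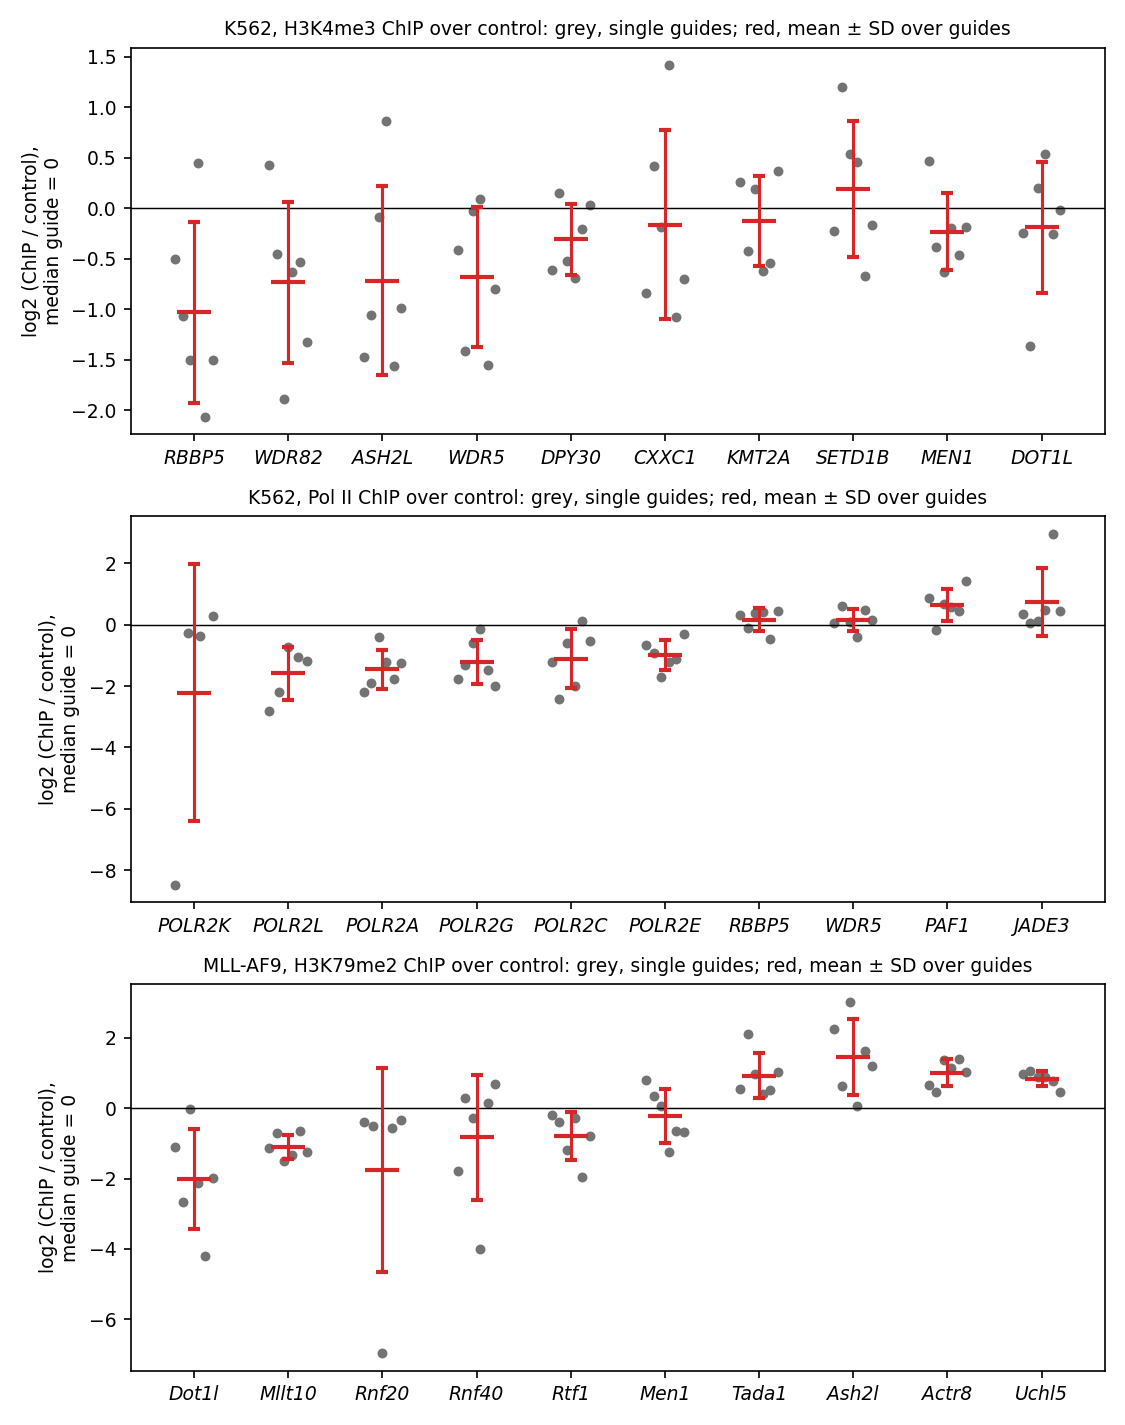
Log2 ratio of ChIP over control reads for single guides (grey points) with the mean and SD over the guides of a gene (red), median guide at 0, in K562 H3K4me3, K562 Pol II and MLL-AF9 H3K79me2. RBBP5 lies at -1.03 in H3K4me3 and at 0.17 in Pol II, POLR2A at -1.46 in Pol II, and Dot1l and Mllt10 at -2.02 and -1.10 in H3K79me2; the means of Rnf20 and POLR2K rest largely on 1 guide each.

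In MLL-AF9 cells the H3K79me2 ChIP asked which regulators alter H3K79 dimethylation, and the enzyme that writes the mark was among the lowest genes. Dot1l (ENSMUSG00000061589), the H3K79 methyltransferase, fell to -2.02 ± 1.41 with 6 of 6 guides below 0 (adjusted permutation p = 0.0153). Its cofactor Mllt10 (AF10) lay at -1.10 ± 0.34, also with 6 of 6 below 0, and Mllt6 at -0.29 ± 0.31. The DOT1L complex list thus had 3 of 3 members below 0 and a median of -1.10, with 0% of 10000 random lists lower; 1 member fell over all genes and 2 fell adjusted over the list alone (Mllt10 at permutation p = 0.0183 after adjustment). H2B ubiquitination and PAF1 genes had a median of -0.42 with 9 of 11 entries below 0 and 0.02% of random lists lower. There the H2B ubiquitin ligase Rnf20 lay at -1.76 ± 2.91, Cdc73 at -1.25 ± 1.12 (a second identifier of that symbol at 0.39 ± 0.41), Rnf40 at -0.83 ± 1.78 and Rtf1 at -0.80 ± 0.68; without the farthest guide Cdc73 lay at -0.75 and Rnf40 at -0.19. None of that list passed over all genes and 1 fell adjusted over the list alone, Rnf20, through 1 guide far below the other 4 (adjusted permutation p = 0.0106; mean -0.46 without it). With 100 control reads the median of the list was -0.18, and 0.96% of random lists were lower.

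H2B deubiquitination and SAGA genes, a list that joins the deubiquitinases with the whole SAGA coactivator complex, had a median of 0.24 with 14 of 16 above 0, above 99.96% of random lists, led by the SAGA core subunits Tada1 at 0.93 ± 0.64 and Supt7l at 0.72 ± 0.57. Eny2 of the deubiquitinase module lay at 0.67 ± 0.94 (0.37 without its farthest guide) and the deubiquitinase Usp51 at 0.52 ± 0.58; 0 passed over all genes and 1, Tada1, rose adjusted over the list alone (permutation p = 0.0221 after adjustment). HUSH, SETDB1 and KAP1 silence transposons and integrated proviruses through H3K9me3. Their list, which also holds Cbx, Suv39h and Ehmt genes and Wiz, had a median of 0.24 with 14 of 16 entries above 0. That median was higher than those of all 10000 random lists. Setdb1 lay at 0.52 ± 0.53, Mphosph8 at 0.50 ± 0.21 and Fam208a at 0.47 ± 0.33, with 0 calls by either adjustment. Without the farthest guide of each gene that median was 0.05 and lay above 77.0% of random lists.

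COMPASS subunits also lay high in H3K79me2. Their median was 0.18 with 12 of 18 above 0, above 95.6% of random lists. Ash2l rose to 1.47 ± 1.08, Hcfc1 to 1.51 ± 1.18 and Wdr5 to 1.24 ± 1.32 over all genes, and 5 members rose adjusted over the list alone, with Rbbp5 at 0.82 ± 0.57 and Setd1a at 0.72 ± 0.35 added. Kmt2a lay at 0.29 ± 0.22 and Men1 at -0.23 ± 0.76. The list lay above 73.2% of random lists with no control-read minimum, 80.3% with 100 control reads and 86.7% with the minimum on mean reads. It lay above 95.9% with the median over guides and 99.2% without the farthest guide. With guides centred on others with like control reads it lay above 99.3%, and above 99.94% when they were also scaled. Histone chaperones and H2A.Z exchange genes had a median of 0.19, above 96.7% of random lists, with 0 calls over all genes and 5 higher adjusted over the list alone, among them Ruvbl1 at 1.10 ± 0.63, Actr6 at 1.08 ± 0.30 and Chaf1b at 1.04 ± 1.37 (0.46 without its farthest guide). Ruvbl2 of that list lay at -1.40 ± 2.55 with 1 guide at 0 ChIP reads, and at 0.48 with the read minimum set on the mean of ChIP and control. Prmt5 at 0.91 ± 0.29 and the CDK-activating kinase subunit Mnat1 at 0.97 ± 0.67 passed adjusted over their lists alone and not over all genes. Control reads per guide were few, from 56 to 312 for Prmt5, 44 to 458 for Mnat1 and 50 to 224 for Actr6. The highest guides of Chaf1b had 43 and 44. The tenth of guides with the fewest control reads, up to 170, had an SD of 1.71. Calls over a list alone were not repeated with guides scaled on like control reads. Pol II and elongation factors had a median of -0.22 with 0.82% of random lists lower, but the median was -0.053, with 7 of 13 below 0, with scaling on non-targeting guides. Polr2a lay at -0.80 ± 2.65 with 3 of 6 guides below 0, and at 0.22 without its farthest guide, which had 0 ChIP reads. The other 12 lists lay between percentiles 8.06 and 81.2.

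Over the 1151 genes tested in H3K79me2, 3 fell and 6 rose, and 97 had an unadjusted p under 0.05. Besides Dot1l, the elongation factor subunit Supt4a fell to -2.63 ± 2.63 (5 of 6 guides below 0) and the kinetochore gene Spc24 to -2.58 ± 3.38 (4 of 5; adjusted permutation p = 0.0046 and 0.0164). Neither passed without the farthest guide, at -2.03 and -1.53. Supt4a lay at -1.12 with 100 control reads and Spc24 at -0.20 as the median over guides, and neither passed there. Besides the COMPASS genes, the chaperonin subunit Tcp1 rose to 1.75 ± 1.21, the snRNA promoter factor Snapc4 to 1.60 ± 1.01 and Actl6a, shared by SWI/SNF and INO80, to 1.31 ± 0.70 (adjusted permutation p between 0.0046 and 0.046 for the 6, with 4 of 4 or 6 of 6 guides above 0 except 3 of 4 for Wdr5). The call of Dot1l was kept in 10 of 12 alternatives and ended with no control-read minimum and without its farthest guide, where its mean was -1.58. The 10 include both scalings, which cannot change a call, and the null from non-targeting guides, with which 197 genes passed. The 6 genes that rose had mean control reads between 90.0 and 310.2 per guide, and 5 of them passed once guides were centred on others with like control reads, but 0 once guides were also scaled on them.

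**Figure D2:**
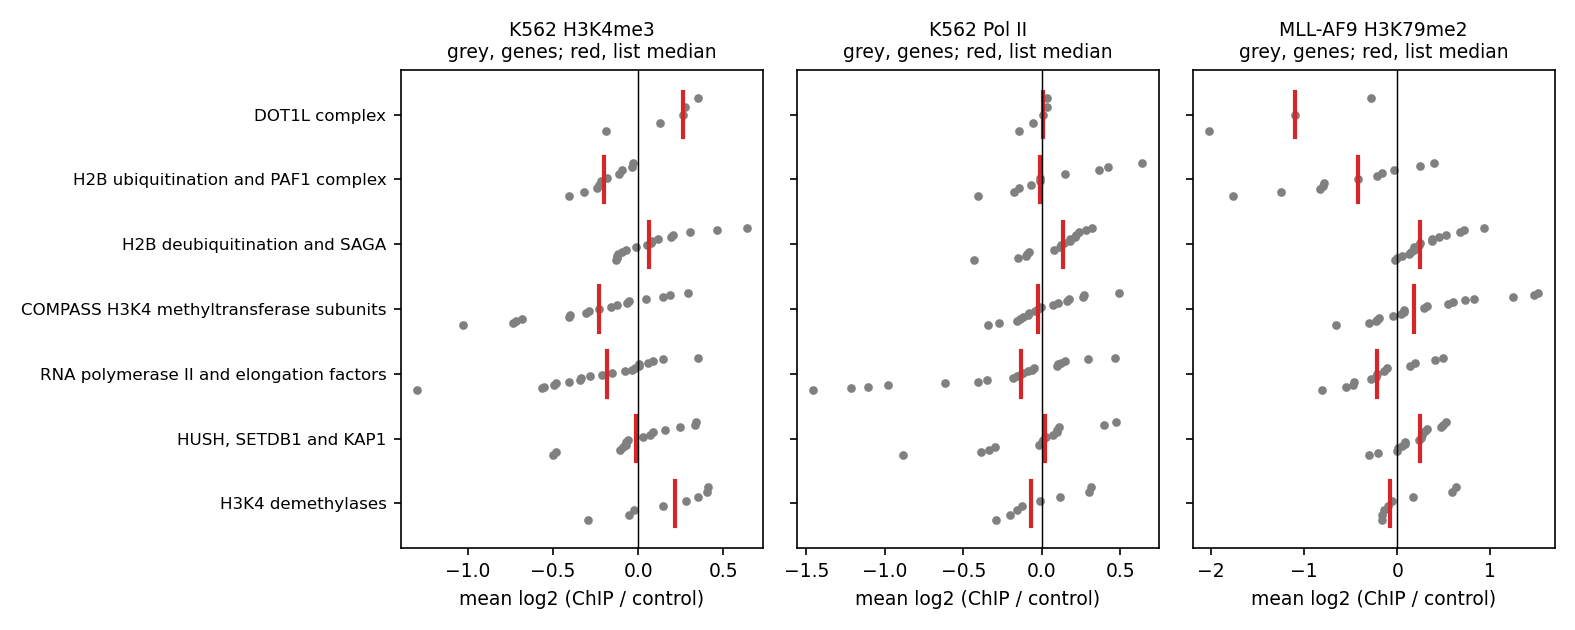
Mean log2 ratio of ChIP over control per gene (grey points) and list median (red line) for 7 of the fixed gene lists in the 3 screens; the horizontal scales differ. The DOT1L complex has a median of -1.10 over 3 mouse genes in H3K79me2. Over 5 human genes in K562 its median is 0.26 in H3K4me3 and 0.01 in Pol II. COMPASS has a median of -0.23 in H3K4me3.

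The mixtures asked how far, and how fast, H3K79me2 at the cassettes of the human-guide K562 cells was lost under SGC0946, with DMSO-treated mouse-guide K562 cells as reference within each tube. In the DMSO mixture human guides made up 71.4% of input reads and 69.0% of H3K79me2 ChIP reads (Wilson 95% intervals 71.3% to 71.4% and 68.95% to 69.02%). Relative to DMSO, the human over mouse ratio of ChIP over input was 0.523 after 24 h (bootstrap interval 0.460 to 0.621), 0.119 after 48 h (0.111 to 0.127), 0.168 after 72 h (0.158 to 0.179) and 0.202 after 96 h (0.180 to 0.235). H3K79me2 at human-guide cassettes was thus 47.7% lower at 24 h and 88.1% lower at 48 h. The human share of ChIP reads was 34.2% at 24 h, 17.9% at 48 h, 19.9% at 72 h and 27.8% at 96 h, and of input reads 52.7%, 67.3%, 62.3% and 68.2%. The 24 h value depends on its input: with all 5 inputs summed it was 0.234, and the order of the times stayed the same. Each time was a single library, and no test across libraries was run.

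**Figure D3:**
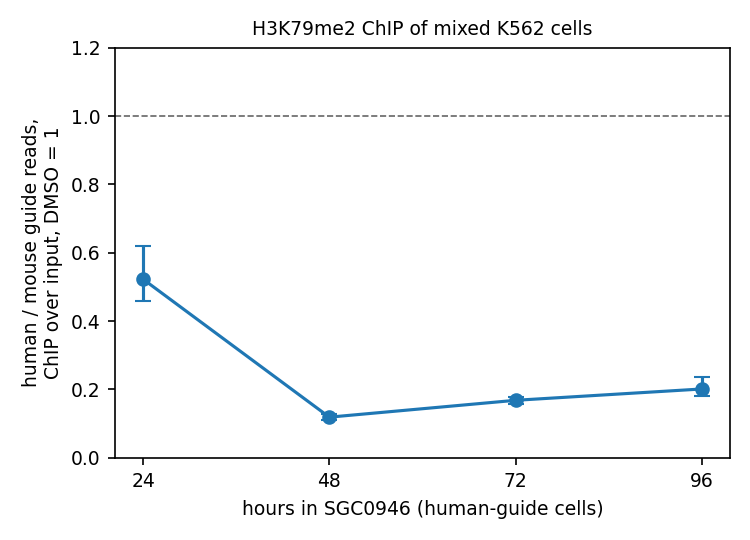
Human over mouse guide reads in the H3K79me2 ChIP divided by the same ratio in the input, with the DMSO mixture at 1 (dashed line), against hours in SGC0946; bars are 95% bootstrap intervals over guides. The ratio is 0.523 at 24 h and between 0.119 and 0.202 from 48 h on.

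Gene effects could be asked in the DMSO mixture only for the 30 genes with 3 or more human guides. Of these, 0 passed the permutation test (1 passed with no control-read minimum, EIF4A3), and 1 gene, RECQL4, had an unadjusted p under 0.05, at -2.76 ± 4.40 over 3 guides. Few reads of each unmixed population fell on guides of the other species. In mouse-guide cells 6412 of 7164322 reads, 0.0895%, fell on 319 human guides (exact binomial 95% interval 0.0873% to 0.0917%), and in human-guide cells 4757 of 6204326 reads, 0.0767%, fell on 195 mouse guides (0.0745% to 0.0789%).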

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

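All tests of the rise between 48 h and 96 h, the test of further COMPASS genes and the centring without scaling were chosen after the results had been seen; the test of control reads on the genes that rose in H3K79me2 was written before its result.

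DHX8 stood out because H3K4me3 and Pol II differed when the difference itself was tested, by 2.74 on the log2 scale (5 of 6 guides above 0). That call was lost in 5 of 12 alternatives, among them 1.41 without the farthest guide, 1.15 with 100 control reads and 0.54 with no control. The last leaves out the guides with 27 and 0 Pol II ChIP reads, since the read minimum falls on that ChIP. The alternatives that kept the call include both scalings, which cannot change a call.

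The human H3K79me2 ratio was 1.69 times as high after 96 h of SGC0946 as after 48 h (bootstrap interval 1.49 to 1.98), and it stood out because permuting species labels over 643 human and 390 mouse guides separated these libraries (log2 difference 0.89), a test that compares the 2 libraries and not the times. A few abundant guides do not account for it: without the 10 most abundant guides of each species the ratio was 1.61 (1.52 to 1.71). Human guides made up 67.3% of input reads at 48 h and 68.2% at 96 h, so the measured input mixes differed little. With all 5 inputs summed the ratio was 1.76 (1.56 to 2.06), but a common input cancels from it. That test therefore cannot exclude a difference in mix that the inputs miss. Processing of the 48 h ChIP library stays open and cannot be told apart from time, because its table alone among the mixtures has a padded layout and the SD of the log2 ratio over its human guides was 2.30, against 1.44 at 72 h and 1.64 at 96 h, with 1 library per time. A change with time in SGC0946, the difference that the design names, stays open as an untested explanation.

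The 6 genes that rose in MLL-AF9 H3K79me2 (Tcp1, Snapc4, Hcfc1, Ash2l, Actl6a and Wdr5) had few control reads, and guides with few reads lay high and varied widely: the tenth of guides with the fewest control reads had a median of 0.39 and an SD of 1.71, against -0.08 and 0.27 in the tenth with the most. With guides centred on others with like control reads and not scaled, 5 of the 6 still passed and Wdr5 did not, so a higher median of guides with few control reads does not account for those 5 calls. With guides also scaled on the spread of such guides, 0 of the 6 passed: Ash2l went from 1.47 ± 1.08 to 1.14 ± 0.89 centred and 1.05 ± 0.64 in scaled units, and Wdr5 from 1.24 ± 1.32 to 0.85 ± 1.38 and 0.94 ± 1.31, with adjusted permutation p of 0.440 and 0.641 once scaled, the highest of ranges that start at 0.000334 over the alternatives of each gene. Few control reads, through the wide spread of such guides, are therefore a candidate explanation of the calls. COMPASS loss stays open: Rbbp5, Dpy30, Cxxc1 and Setd1a, scaled in the same way, had a median higher than 99.86% of random sets of 4 genes, but they were chosen after their values had been seen and Rbbp5 and Setd1a had already passed over their list alone, so that value decides nothing.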

How the results depend on the processing

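Guide ranks, centring and scaling on like control reads (20 bins), centring alone, H3K4me3 over Pol II reads with no control, and the alternatives of list medians were chosen after seeing the data; the others were planned. Each group holds 1 library, so no paired test of a single ChIP against its control was possible. Each mixture ChIP was divided by the input of its time, and no test across those pairs was run. Of the values of single genes under alternatives, 993 kept their direction and side of the threshold, 91 passed it newly, 55 no longer passed and 11 reversed. Scaling by total reads and by non-targeting guides could not move a gene across the threshold or change a count, and gave 93 and 91 of the 993. Of the 91 new passes, 56 came from the null from non-targeting guides. Of the counts of genes past the threshold, 43 stayed within 1.5 times the reported count and 28 moved further, and of the list medians 67 stayed within that factor and 16 moved further. Of the mixture ratios 13 stayed inside their bootstrap intervals and 7 did not. The null from non-targeting guides was not run in the DMSO mixture, which has too few such guides. Where no reason is given, the cause was not tested. In the tenth of guides with the fewest control reads the SD was 1.00 in H3K4me3, 1.14 in Pol II and 1.71 in H3K79me2. In the tenth with the most it was 0.50, 0.33 and 0.27, so genes with few control reads have the widest errors.

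With no control-read minimum, 0 genes passed in H3K4me3 (2 as reported), 2 in H3K79me2 (9 as reported) and 1 in the DMSO mixture (0 as reported). With 100 control reads the counts were 1 in H3K4me3, 3 in H3K79me2 and 0 for H3K4me3 minus Pol II (1 as reported), and in H3K79me2 the H2B ubiquitination and PAF1 list lay at -0.18 and COMPASS at 0.085. With the minimum on mean reads 0 passed in H3K4me3, 5 in H3K79me2 and 1 in the DMSO mixture, Ruvbl2 lay at 0.48 and the H2B ubiquitination and PAF1 list at -0.23 in H3K79me2. With the median over guides, 9 genes passed in Pol II (0 as reported) and 16 in H3K79me2, where the H2B ubiquitination and PAF1 list lay at -0.26 and HUSH at 0.12. Without the farthest guide, 23 of 92 values of single genes were smaller in size by over 1.5 times, 6 larger and 5 reversed; 4 genes passed in H3K79me2 (0 lower, 4 higher, against 3 and 6) and 0 for the difference. There SETD1B lay at -0.014, DOT1L at 0.047 and COMPASS at -0.37 in H3K4me3, ASH2L at -0.14 in Pol II and POLR2K at -0.48 in the difference. In H3K79me2 Polr2a then lay at 0.22, the H2B ubiquitination and PAF1 list at -0.18 and HUSH at 0.047.

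With the null from non-targeting guides, 108 genes passed in H3K4me3 (106 lower, 2 higher), 30 in Pol II (28 lower, 2 higher), 197 in H3K79me2 (38 lower, 159 higher), 31 between the controls (31 lower; 0 as reported) and 28 for the difference (16 lower, 12 higher). Those guides had medians of 0.19 in H3K4me3, 0.12 in Pol II, -0.17 in H3K79me2 and 0.09 between the controls, away from the median guide, so the null is off centre. Scaling on non-targeting guides shifted all values of a screen. SETD1B then lay at -0.000801, COMPASS at -0.42 and the H2B ubiquitination and PAF1 list at -0.39 in H3K4me3, and ASH2L at -0.024 and the Pol II and elongation list at -0.25 in Pol II. In H3K79me2 the H2B ubiquitination and PAF1 list lay at -0.25, SAGA at 0.41, HUSH at 0.41 and COMPASS at 0.35. With guide ranks, 1 gene passed in H3K4me3, 9 in Pol II, 3 for the difference and 13 in H3K79me2 (4 lower, 9 higher), of which 4 were among the 9 reported. With centring and scaling on like control reads, 1 passed in H3K4me3, SNAPC4, and 0 of the reported genes did. None passed there for the difference. With centring alone 10 passed in H3K79me2 (4 lower, 6 higher), 8 of them as reported. With no control, 13 passed for the difference (2 lower, 11 higher) and POLR2K lay at -0.13. There the read minimum fell on the Pol II ChIP and left out the POLR2K guide with 0 reads in it.

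Over the other K562 control, 1 gene passed in H3K4me3 (SNAPC4, and 0 of the reported genes) and 2 in Pol II. There KDM1A lay at 0.014 and PAF1 at 0.11 in H3K4me3, and the Pol II and elongation list at -0.25 in Pol II. Over the summed controls, 0 passed in H3K4me3 and 1 in Pol II. With all 5 inputs summed, the human H3K79me2 ratio was 0.234 at 24 h, 0.0982 at 48 h, 0.112 at 72 h and 0.173 at 96 h; as the median over guides it was 0.105 at 48 h, 0.144 at 72 h and 0.177 at 96 h.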

Other observations

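The INO80, PRMT5, splicing, Mediator, Integrator and TFIID lists, the genes named here the scaling on control reads and the splicing values over single controls were chosen after values had been seen; the tests on SNAPC4, BDP1 and the further splicing factors were written before their results.

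With guides scaled on others with like control reads, the H3K79me2 screen in MLL-AF9 cells called 2 lower and 4 higher genes. Dot1l and Mllt10 were lower with 6 of 6 guides below 0 each. Higher were Uchl5 and Actr8, both subunits of the INO80 remodelling complex, Hira, a chaperone of histone H3.3, and Chd1, a remodeller that reads H3K4me3, each with 6 of 6 guides above 0. As plain log2 ratios Uchl5 lay at 0.83 ± 0.21 and Actr8 at 1.01 ± 0.38. The INO80 complex had a median of 0.17, above 98.6% of random lists, with 2 members higher adjusted over the list alone. The PRMT5 complex, of 2 genes, lay at 0.66, above 88.3% of random lists. Wdr77 lay at 0.42 ± 2.68 over 6 guides as reported and did not pass over all genes. It passed at 1.50 ± 0.54 over 5 guides with 100 control reads, and also with the median over guides and without the farthest guide. TFIID genes in H3K79me2 had a median of 0.33 with 7 of 8 above 0, above 95.7% of random lists.

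In K562, TFIID and Mediator genes lay low in the Pol II ChIP, with 13 of 14 and 19 of 24 members below 0, medians of -0.18 and -0.13, and 1.96% and 1.97% of random lists lower. The single TFIID gene that passed adjusted over the list alone, a list chosen after the values had been seen, went the other way: TBP lay at 0.60 ± 0.53 with 5 of 6 guides above 0 (adjusted permutation p = 0.0484) and at 0.29 over the other control. Integrator lay at 0.13, above 98.3% of random lists, with INTS8 at 0.72 ± 0.77 and 6 of 6 guides above 0 (0.42 without its farthest guide); the list lay at 0.0032 with scaling on non-targeting guides. Splicing factors lay at -0.09 and INO80 genes at 0.04 in Pol II. When H3K4me3 reads were divided by Pol II reads with no control, 2 genes were lower and 11 higher. The core COMPASS gene ASH2L was lower at -1.18 ± 0.82 with 6 of 6 guides below 0, as was ASCL2 at -1.19 ± 1.80. The higher genes were POLR2C, POLR2E, POLR2G, POLR2H, POLR2L, RUVBL1, MED6, GTF2A1, EIF4A3, PCNA and SF3B3, with POLR2G at 1.50 ± 0.85 and RUVBL1 at 1.33 ± 0.58. DHX8 was not among them, at 0.54, but the read minimum, here set on the Pol II ChIP, left out its guides with 27 and 0 reads there.

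SNAPC4 encodes a subunit of the complex that binds snRNA promoters and the U6 promoter, a promoter commonly used to drive guide cassettes. Its guides lay at 0.72 ± 0.83 in K562 H3K4me3, at 1.01 ± 0.84 over the other control, where it passed the threshold (adjusted permutation p = 0.0456, in a range of 0.0228 to 0.472 over the alternatives), and at 0.89 ± 0.82 over the summed controls, with 5 of 6 guides above 0 in each. In K562 Pol II SNAPC4 lay at 0.24 ± 0.17. In mouse H3K79me2 Snapc4 lay at 1.60 ± 1.01 over 4 guides with a mean of 90.0 control reads. Snapc4 did not pass there once guides were scaled on like control reads (adjusted permutation p = 0.582). SNAPC4 guides did not have few control reads in K562: their mean was 881 in the control of the H3K4me3 ChIP, where the median guide had 704. After scaling on like control reads, over the summed controls, SNAPC4 lay 5.19 SD above the mean of all genes. With control reads that high, the test had little room to come out otherwise and decides nothing on its own. A hypothesis was that loss of U6 promoter factors as a class raises H3K4me3 at the cassette. BDP1, a TFIIIB subunit, did not bear it out, at -0.32 ± 0.93 and percentile 8.60 of all genes over the summed controls. TBP, which was not part of that test, lay at -0.01 ± 0.72 and percentile 48.9 there. Single genes cannot decide for the class. An effect of SNAPC4 alone is possibly biological, as a hypothesis from a single library.

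A second hypothesis was that splicing factor loss as a group goes with higher H3K4me3 guide reads, prompted by PHF5A (0.81 ± 0.23 over the summed controls), DHX8 (0.73 ± 1.03), CDC5L (0.46 ± 0.44) and SF3B3 (0.37 ± 0.98). The 10 other splicing factor genes had a median of 0.16, above 98.2% of random lists, over the summed controls. Over the control of the H3K4me3 ChIP these 10 lay at -0.0053, above 52.8% of random lists. There the whole list of 14 lay at 0.11, above 88.4%, and at -0.08 with scaling on non-targeting guides. In control against control the list lay at -0.09, above 9.21%. The result thus depends on the control used, and the hypothesis stays open.

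Non-targeting guides differed from gene-targeting ones in the 3 screens and between the controls. Their median was 0.19 in H3K4me3, 0.12 in Pol II, -0.17 in H3K79me2 and 0.09 in control against control. A resampling test set the mean of the class against 100000 draws of as many guides, with replacement, from the class and gene-targeting guides together. Its adjusted p was 0.00040, 0.00412, 0.0106 and 0.00677 in that order, over 8 such comparisons. Guides against safe regions had medians of 0.05, 0.02, 0.01 and 0.02 and did not pass in any.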
